A study of Bos taurus with 13 samples.

How the data were processed

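Testis RNA of 13 newborn bull calves was measured on Affymetrix arrays, 1 array per calf. The dams were Angus cross cows that had free access to a mineral mix with 35 ppm of selenium from 4 months before breeding until calving. The selenium was sodium selenite (inorganic, ISe, 5 calves), a selenium yeast product (organic, OSe, 4 calves) or a mixture with 50% from each source (Mix, 4 calves). The labels describe 24 cows, 8 per treatment, and testis collection within 2 days of birth. Each array was placed in its group by its title, and every array came from a different calf, so the spread between arrays includes the spread between animals.

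The deposited values were log2 expression values, 1 per probe set and array, made by the authors. Biotin-labelled cRNA was prepared from Trizol-extracted total RNA with oligo(dT) priming, per the labels' protocols. GCOS 1.2 and Partek 6.4 were named as software, per the submitters' processing notes, without saying which step each one did. The background correction, the summary over probes and the normalization between arrays were not given in the sources used here. The log2 scale was read from the values, which ran from 2.07 to 14.6. Whether and how the arrays had been centred stayed unknown. The array medians were 7.64, 7.64, 7.63, 7.62 and 7.63 for ISe animals 1 to 5, 7.64, 7.74, 7.62 and 7.63 for OSe animals 1 to 4, and 7.65, 7.64, 7.64 and 7.61 for Mix animals 1 to 4. Scanner files were not used here. Signal over background could therefore not be computed, and the number of arrays limits the precision.

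The table held 26773 probe sets. The platform annotation gave exactly 1 gene symbol to 18550 of them, several symbols to 595 and none to 7628. A probe set listing 1 symbol under several gene identifiers was taken as 1 symbol. Of 18166 probe sets with a single gene identifier, 17996 matched the reference gene table (assembly ARS-UCD2.0), and this changed 0 symbols. No coordinates were taken from that table, because the array files name no build. No gene was named from a probe set with several symbols. The design called for leaving control probe sets out. None was marked as such in the value table or the annotation, so all 26773 were tested, and a run on probe sets with exactly 1 symbol was added after seeing the data. There were 297 probe sets whose values were identical to those of another probe set, and 0 pairs of identical arrays. Correlations between arrays across probe sets ran from 0.979 to 0.991.

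All 13 arrays were fitted in 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 3.28). Differences among the 3 forms were tested with the moderated F test. The 4 contrasts were OSe minus ISe, Mix minus ISe, Mix minus OSe, and Mix minus the midpoint of ISe and OSe. All p-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Errors of changes are standard errors (SE) from this fit, and errors of group means are standard deviations (SD). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

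A set of 25 gene lists covering testis cell types, selenium biology, antioxidant defence, metabolism and stress responses was fixed before the data were examined, as were the contrasts, the alternatives and the rule for named genes. For lists, each gene was represented by its probe set with the highest mean, which left 18087 genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists within a contrast. Camera asks whether a list moved relative to all other genes. Beside it stand camera with a correlation estimated from the arrays, fry, which tests whether the genes of a list moved on balance in a given direction, and an exact two-sided permutation test of each list's mean per calf. The permutation test was added after seeing the data. Where a p is given as adjusted over a list alone, it does not correct for the other lists or contrasts. Some members with such a p under 0.05 are therefore expected by chance.

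The rule for named genes took, in each comparison of a pair of groups, the 10 genes with the largest change in each direction among those past the threshold. Where fewer passed, places were filled by the smallest unadjusted p, among probe sets with exactly 1 symbol other than placeholder names and with a mean above the 25th percentile (6.26 on the log2 scale). It added up to 4 members of each list described, by smallest p, and 14 testis and selenium genes fixed in advance. STAR, the protein that carries cholesterol into mitochondria, was among these 14, but its only probe set was shared with other genes, so 13 were reported.

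The tests were checked on simulated data drawn from the means and spreads of the 26773 probe sets. With changes of 0.5, 1 and 2 on the log2 scale planted in 67, 67 and 66 of them, the test of OSe against ISe recovered 40.3%, 92.5% and 98.5% of them. For Mix against ISe the shares were 41.8%, 79.1% and 98.5%, and for Mix against OSe 44.8%, 83.6% and 97.0%. A planted shift of 0.2 in 1 gene list of 25, simulated for Mix against OSe over 18087 genes, was called and 0 other lists were called. Among 26573 unchanged probe sets, 8, 8 and 12 were called in the same order of comparisons. The simulated genes were independent, which the measured genes are not. The planted changes also shared 1 adjustment, and the Benjamini-Hochberg threshold is stricter where fewer probe sets change. The shares recovered therefore do not tell how often a change would be found if few probe sets changed. In the measured values of Mix against OSe, 43 probe sets changed by over 1 on the log2 scale and 0 passed.

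Alternatives were quantile normalization, centring of array medians, leaving out the dimmest 25% or 50% of probe sets, a trended and robust prior, an unmoderated linear model, array weights, only the arrays of the groups compared, 1 probe set per gene, the animal number as a block, a threshold of 0.10, the mean of all probe sets of a gene, and leaving out each calf in turn. The similarity of the OSe and Mix changes was set against unchanged groups simulated by dealing the within-group deviations of the 13 arrays out to groups of the same sizes, with random signs. This form was chosen after the outputs of earlier forms had been seen, and the closing section gives all of them. Calves of different groups share numbers in the labels. Whether these numbers pair the calves is checked among the alternatives. An RNA quality covariate had been planned and was not run, since the probe sets it needs were not marked.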

Results

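The series asked whether the chemical form of selenium given to pregnant cows was reflected in gene expression in the testes of their newborn sons. Testes of 5 ISe calves, 4 OSe calves and 4 Mix calves were profiled, each on its own array. Hormone genes of the somatic testis cells were among the brightest. INSL3, the Leydig cell hormone of testis descent, reached 13.45 ± 0.09 (SD, n = 5) on the log2 scale in ISe, 13.38 ± 0.36 (n = 4) in OSe and 13.50 ± 0.20 (n = 4) in Mix. AMH, the Sertoli cell hormone that regresses the Müllerian ducts, stood at 12.52 ± 0.10 (n = 5), 12.51 ± 0.27 (n = 4) and 12.39 ± 0.24 (n = 4). The array of OSe animal 2 had a median of 7.74, against 7.61 to 7.65 on the other 12 arrays.

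RNF141, a RING finger protein, and ACOX3, a peroxisomal acyl-CoA oxidase, were among the genes that differed most by p among the 3 selenium forms, and no probe set passed the test. In limma's moderated F test, 0 of 26773 probe sets passed an adjusted p of 0.05, and 1206 had an unadjusted p under 0.05, where chance gives 1338.65. The unmoderated linear model gave 0 and 1112. RNF141 had the lowest adjusted p of 0.56, and ACOX3 had 0.95. Without OSe animal 3, 1 probe set without a gene symbol passed (adjusted p = 0.0328). The steroidogenic enzyme CYP17A1 measured 11.29 ± 0.24 (SD, n = 5) in ISe, 11.58 ± 1.03 (n = 4) in OSe and 11.36 ± 0.69 (n = 4) in Mix. CYP11A1, which cuts the cholesterol side chain, measured 9.92 ± 0.30, 10.21 ± 0.80 and 10.48 ± 0.69 in the same order. HSD3B1, the next enzyme of steroid synthesis, measured 10.07 ± 0.12, 10.38 ± 0.36 and 10.02 ± 0.23. LHCGR, the luteinizing hormone receptor, measured 11.05 ± 0.28, 11.11 ± 0.34 and 11.10 ± 0.24. SOX9, the transcription factor of Sertoli cells, measured 8.54 ± 0.18, 8.84 ± 0.25 and 8.52 ± 0.11. The germ cell helicase DDX4 measured 8.81 ± 0.40, 8.59 ± 0.55 and 9.11 ± 0.41. Among selenoproteins, GPX1 measured 12.74 ± 0.06, 12.70 ± 0.16 and 12.72 ± 0.11, and GPX4, which protects membranes from lipid peroxides, 10.55 ± 0.11, 10.50 ± 0.24 and 10.57 ± 0.14. The selenium carrier SELENOP measured 10.84 ± 0.13, 10.76 ± 0.19 and 10.73 ± 0.22. TXNRD1, a thioredoxin reductase, measured 9.27 ± 0.06, 9.31 ± 0.12 and 9.16 ± 0.05, and SELENOW 10.64 ± 0.10, 10.53 ± 0.11 and 10.59 ± 0.09. The lowest adjusted p of the F test among these 13 genes was 0.954.

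OSe was compared with ISe to ask whether the organic form differed from the inorganic one. Genes of cholesterol synthesis and uptake lay higher in OSe, with 19 of 20 measured members above ISe and a median change of 0.25 (camera adjusted p = 1.49e-05). The call was lost with an adjusted p = 0.947 with an estimated correlation. It also rested on OSe animal 3, without which the list mean went from 0.26 to 0.04 (adjusted p = 0.93). The first members by p were HSD17B7 at 0.35 ± 0.14 (SE), NSDHL at 0.45 ± 0.23, PMVK at 0.25 ± 0.12 and TM7SF2 at 0.43 ± 0.24, all enzymes of the pathway. Without OSe animal 3, NSDHL was at 0.12 and TM7SF2 at 0.09. Collagen and extracellular matrix genes lay lower, in 28 of 39 members, with a median of -0.05 (camera adjusted p = 0.0037; adjusted p = 0.947 with an estimated correlation). Among them LOXL1, which cross-links elastic fibres, was at -0.32 ± 0.12 and the basement membrane protein NID1 at -0.29 ± 0.11, while COL18A1 was at 0.10 ± 0.07 and the growth factor receptor PDGFRA at -0.17 ± 0.12. Gonocyte and spermatogonium genes lay lower in 26 of 42 members, with a median of -0.04 (camera adjusted p = 0.00971; adjusted p = 0.947 with an estimated correlation). Members included the RNA-binding protein DAZL at -0.27 ± 0.18, UCHL1 at -0.21 ± 0.15, NANOS2 at -0.13 ± 0.11 and TEX101 at -0.14 ± 0.09. The collagen call ended without ISe animal 1 or 3 or OSe animal 1 or 3 (adjusted p 0.0585, 0.255, 0.0946 and 0.708). The gonocyte call ended without ISe animal 2 or 4 or OSe animal 2 or 4 (0.227, 0.389, 0.483 and 0.164) and after quantile normalization (0.0551). The collagen mean of -0.05 went to -0.02 (ISe animal 3), -0.01 (OSe animal 1), 0.03 (OSe animal 3), -0.10 (ISe animal 4) and -0.16 (OSe animal 2) without the calf named. The gonocyte mean of -0.06 went to -0.0026 (ISe animal 4), -0.03 (ISe animal 2), -0.03 (OSe animal 2), -0.03 (OSe animal 4), -0.15 (ISe animal 3) and -0.13 (OSe animal 1). COL18A1 was at 0.04 and PDGFRA at -0.10 without OSe animal 1, and DAZL was at -0.16 and PDGFRA at -0.26 without OSe animal 2. UCHL1 was at -0.08 and TEX101 at -0.07 without OSe animal 3, UCHL1 at -0.31 without ISe animal 3, and NANOS2 at -0.04 without OSe animal 4.

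No single gene passed the test in OSe against ISe. In limma, 0 of 26773 probe sets had an adjusted p under 0.05 (lowest 0.9999), and 701 had an unadjusted p under 0.05, 512 higher and 189 lower in OSe. The unmoderated model gave 0 and 679. After quantile normalization the split was 381 higher and 332 lower, and after median centring 376 and 313. The glutathione synthetase GSS was higher in OSe by 0.28 ± 0.06 (SE, 1.21-fold), with no overlap between the groups. It was the only member of the 42 measured antioxidant genes with a p under 0.05 when adjusted over the list alone (0.0307). Over all genes 0 passed. The adjustment over the list alone leaves out the other lists and contrasts, so chance is not excluded for GSS. Other genes chosen by p did not overlap either, and the share over all probe sets is not given here. The glutathione transferases GSTA4 and GSTA2 were at 0.25 ± 0.09 and 0.84 ± 0.39, and GSTA1 at -0.36 ± 0.23. GSTA2 was at 0.54 without ISe animal 2, and GSTA1 at -0.19 without OSe animal 1. The other genes first by rank in OSe were the histone gene H2BC4 (0.45 ± 0.10), ENPP5 (0.44 ± 0.10), the heat shock protein HSPA1A (0.70 ± 0.19), ZNF75A (0.39 ± 0.11), the fatty acid elongase ELOVL6 (0.38 ± 0.11), the sodium channel SCN3A (0.49 ± 0.15), complement C4A (0.35 ± 0.11), VTI1A (0.29 ± 0.09) and MOG (0.40 ± 0.13). On the lower side stood the sulfotransferase CHST7 (-0.30 ± 0.08), the chemokine CCL24 (-0.35 ± 0.09), MAGEB4 (-0.78 ± 0.22), the chloride transporter CLCN4 (-0.31 ± 0.11), CMTM5 (-0.25 ± 0.09), RELL2 (-0.28 ± 0.10), MS4A18 (-0.46 ± 0.17), MLC1 (-0.18 ± 0.07), AIG1 (-0.25 ± 0.09) and LOXL1. H2BC4, HSPA1A, C4A and MAGEB4 belong to families of near-identical genes, so their probe sets may not be specific to 1 copy. MLC1 was dim, with an ISe mean of 6.425, near the 25th percentile of 6.26, and its other probe set did not change in the same direction.

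In OSe against ISe, selenoproteins were higher in 14 of 25 members, with a median of 0.012 and a mean of -0.0022, and camera's direction was down (adjusted p = 0.502). The plasma glutathione peroxidase GPX3 was at -0.23 ± 0.09 (SE), SELENOT at 0.14 ± 0.09 and SELENOV at 0.11 ± 0.09. SELENOV was at 0.07, 0.17 and 0.04 without ISe animal 1, ISe animal 3 and OSe animal 2, and SELENOW went from -0.11 to -0.07 without OSe animal 3. Genes of selenium handling had a median of 0.02 over 22 members (adjusted p = 0.868), with SELENBP1 at 0.27 ± 0.19, RPL30 at 0.12 ± 0.08, the selenocysteine lyase SCLY at 0.20 ± 0.14 and SARS1 at 0.11 ± 0.09. Without ISe animal 4, SELENBP1 was at 0.11 and SCLY at 0.10, and without OSe animal 3 SCLY was at 0.13 and SARS1 at 0.04. Leydig cell and steroidogenesis genes were higher in 20 of 26 members with a median of 0.08 (adjusted p = 0.25). The lipoprotein receptor SCARB1 was at 0.27 ± 0.12, HSD3B1 at 0.31 ± 0.15, NR5A1 at 0.19 ± 0.10 and SRD5A2 at -0.26 ± 0.11. HSD3B1 was at 0.17 and SCARB1 at 0.16 without OSe animal 3, and SRD5A2 at -0.14 without OSe animal 4. Sertoli cell genes were higher in 19 of 27 members with a median of 0.06 (adjusted p = 0.364), with SOX9 at 0.31 ± 0.12, NR0B1 at 0.17 ± 0.09, SOX8 at 0.15 ± 0.10 and FST at -0.16 ± 0.10. SOX8 was at 0.08 and FST at -0.09 without OSe animal 2, and SOX8 at 0.22 without OSe animal 3. In all, 22 of 25 lists were not called, with adjusted p-values from 0.187.

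**Figure D1:**
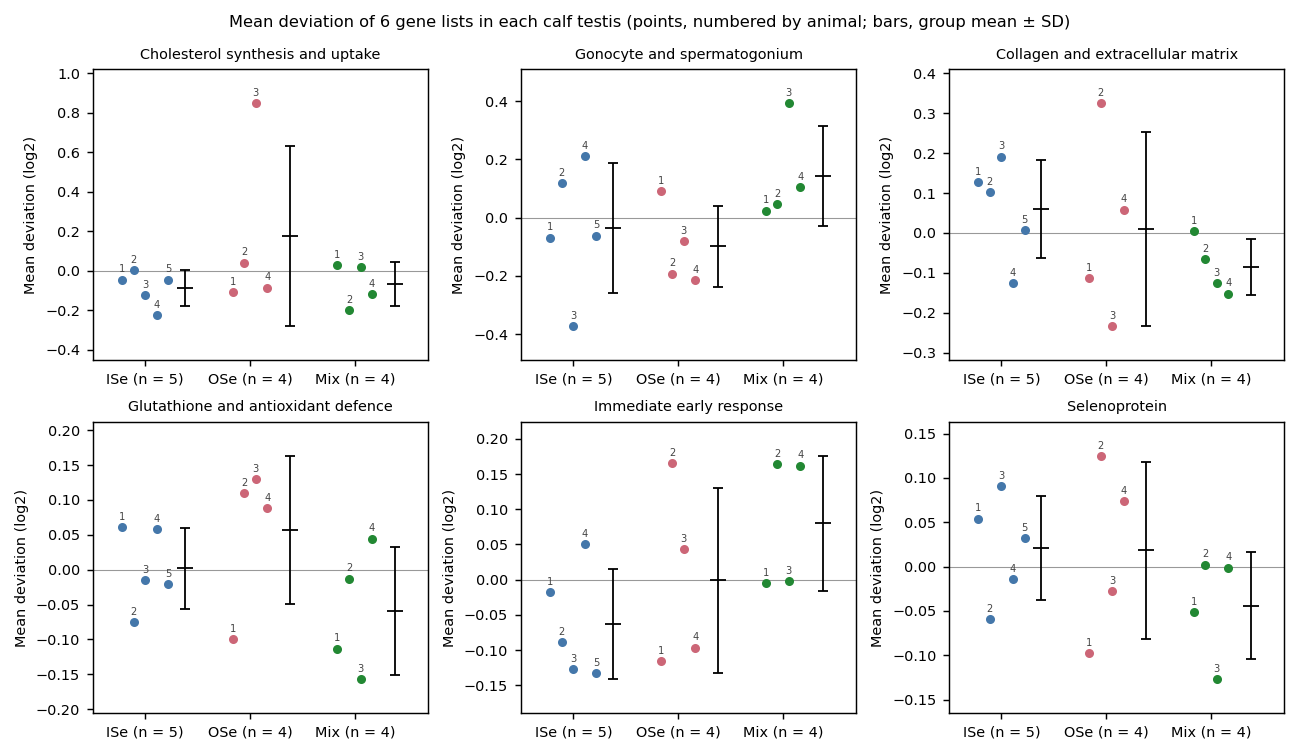
Mean deviation of 6 gene lists from the mean of the 13 calves (vertical axis, log2 scale) in each calf testis, by maternal selenium form; points are calves numbered as in the labels and bars are group mean ± SD. In the cholesterol list OSe animal 3 lies at 0.85 and the other 12 calves lie between -0.22 and 0.04.

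Mix was compared with ISe to ask whether replacing part of the selenite by the organic form was accompanied by a difference. Gonocyte and spermatogonium genes lay higher in Mix, in 37 of 42 members with a median of 0.19 (camera adjusted p = 8.08e-06; adjusted p = 0.71 with an estimated correlation). The first members were DNMT3L, a cofactor of germline DNA methylation (0.23 ± 0.09, SE), ZBTB16, a transcription factor of undifferentiated spermatogonia (0.39 ± 0.15), the GDNF receptor GFRA1 (0.40 ± 0.18) and MOV10L1 (0.35 ± 0.16). The mean deviation of the list per calf ran from -0.373 to 0.212 in ISe and from 0.0242 to 0.394 in Mix. The groups thus overlapped, and the exact permutation p of the list mean was 0.262. The list mean change went from 0.18 to 0.09 without ISe animal 3 (adjusted p = 0.00823) or Mix animal 3 (adjusted p = 0.0271), and the call held. MOV10L1 was at 0.22 without either calf left out singly, and GFRA1 at 0.25 without Mix animal 3. Collagen and extracellular matrix genes lay lower in 32 of 39 members with a median of -0.10 (camera adjusted p = 5.35e-05; adjusted p = 0.71 with an estimated correlation). They included lumican, LUM, at -1.12 ± 0.43, COL1A1 at -0.43 ± 0.19, NID1 at -0.29 ± 0.11 and LAMC1 at -0.17 ± 0.08. Immediate early genes lay higher in 28 of 32 members with a median of 0.12 (camera adjusted p = 5.43e-05; adjusted p = 0.694 with an estimated correlation), among them SOCS3 at 0.29 ± 0.09, JUNB at 0.31 ± 0.11, EGR2 at 0.23 ± 0.12 and FOSL1 at 0.26 ± 0.15. EGR2 was at 0.14 without ISe animal 3, and FOSL1 at 0.14 without ISe animal 5 and 0.12 without Mix animal 2. Inflammation and acute phase genes lay higher in 26 of 35 members with a median of 0.09 (camera adjusted p = 8.75e-04; adjusted p = 0.373 with an estimated correlation). Examples were TNFAIP3, a brake on NF-κB signalling (0.23 ± 0.08), the granulocyte proteins S100A9 (0.26 ± 0.10) and S100A8 (0.53 ± 0.23), and C4A (0.26 ± 0.11). S100A8 was at 0.34 without Mix animal 3.

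Selenoproteins lay lower in Mix than in ISe in 18 of 25 members, with a median of -0.06 (camera adjusted p = 0.035; adjusted p = 0.71 with an estimated correlation). GPX3 was lower by -0.36 ± 0.09 (SE, 1.29-fold), with no overlap between the groups, as for other genes chosen by p. It was the only member with a p under 0.05 when adjusted over the list alone (0.0311), which leaves out the other lists. The deiodinase DIO3 was at -0.47 ± 0.25, SELENON at -0.19 ± 0.10 and TXNRD1 at -0.11 ± 0.07. Glutathione and antioxidant genes lay lower in 30 of 42 members with a median of -0.05 (camera adjusted p = 0.035; adjusted p = 0.71 with an estimated correlation). These included the quinone reductase NQO1 at -0.60 ± 0.17, the extracellular superoxide dismutase SOD3 at -0.65 ± 0.23, GSTP1 at -0.28 ± 0.12 and catalase, CAT, at -0.19 ± 0.11. Oxidative phosphorylation genes lay lower in 48 of 69 members with a median of -0.04 (camera adjusted p = 0.035; adjusted p = 0.738 with an estimated correlation), with NDUFA6 at -0.22 ± 0.08, UQCR10 at -0.18 ± 0.09, NDUFC2 at -0.19 ± 0.11 and NDUFA9 at 0.13 ± 0.08. The selenoprotein call ended without ISe animal 3, 4 or 5 or Mix animal 1 or 3 (adjusted p 0.181, 0.0605, 0.0966, 0.207 and 0.359), and the antioxidant call without ISe animal 1 or 4 or Mix animal 1 or 3 (0.152, 0.105, 0.25 and 0.469). The oxidative phosphorylation call ended without ISe animal 4 or 5 or Mix animal 1 or 3 (0.0779, 0.224, 0.142 and 0.359), and quantile normalization ended all 3 (0.0505, 0.0995 and 0.19). Without Mix animal 3 the selenoprotein mean went from -0.06 to -0.04, the antioxidant mean from -0.06 to -0.03 and the oxidative phosphorylation mean from -0.04 to -0.02. Without Mix animal 4 the antioxidant mean was -0.10, CAT was at -0.12 and UQCR10 at -0.11. NDUFC2 was at -0.12 without Mix animal 1, and DIO3 at -0.31 without Mix animal 2.

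No single gene passed the test in Mix against ISe. In limma, 0 of 26773 probe sets had an adjusted p under 0.05 (lowest 0.967), and 995 had an unadjusted p under 0.05, 459 higher and 536 lower in Mix. The unmoderated model gave 0 and 945, and without ISe animal 4 the unadjusted count was 1731. RNF141 was lower in Mix by -0.81 ± 0.14 (SE, 1.76-fold), at 9.06 ± 0.33 (SD) against 9.88 ± 0.16. Also lower were ZP2, known as an egg coat glycoprotein (-0.51 ± 0.10), ZNF572 (-0.33 ± 0.07), ACOX3 (-0.36 ± 0.08), ZNF461 (-0.42 ± 0.10), CHST7 (-0.33 ± 0.08), MOCS2 of molybdenum cofactor synthesis (-0.31 ± 0.08), the kinase CAMK1D (-0.43 ± 0.11) and the microRNA locus MIR374B (-0.45 ± 0.12). First by rank on the higher side were MCTP2 (0.36 ± 0.08), HOXB9 (0.32 ± 0.08), the semaphorin SEMA3D (0.89 ± 0.23), PRSS12 (0.52 ± 0.14), INSM1 (0.28 ± 0.08), the transporter SLC43A3 (0.24 ± 0.07), SHOX (0.31 ± 0.09), PRDM15 (0.24 ± 0.07), the lysophosphatidic acid receptor LPAR2 (0.36 ± 0.11) and SOCS3. HOXB9, INSM1 and SHOX were dim, with ISe means of 6.33, 6.52 and 6.53, near the 25th percentile of 6.26, while PRSS12 was at 9.14. The lower quartile of the values was 6.30, 6.29, 6.25 and 6.26 in Mix animals 1 to 4. In ISe animals 1 to 5 it was 6.22, 6.26, 6.23, 6.25 and 6.24. Among lymphocyte genes, whose list was not called (adjusted p = 0.418), the immunoglobulin J chain JCHAIN was at -0.28 ± 0.07. It had the only p under 0.05 when adjusted over the list alone (0.0477), which leaves out the other lists. The granzyme GZMB was at -0.31 ± 0.13, CD79B at 0.21 ± 0.11 and MS4A1 at 0.30 ± 0.16, and GZMB was at -0.20 without Mix animal 3. Leydig cell genes had a median of 0.0047 and a mean of 0.03, with camera's direction down (adjusted p = 0.985), and CYP11A1 was at 0.56 ± 0.36, CYP19A1 at 0.30 ± 0.17, NR2F2 at -0.22 ± 0.13 and SULT1E1 at 0.20 ± 0.09. Sertoli cell genes had a median of -0.01 (adjusted p = 0.601), with INHBA at -0.22 ± 0.12, transferrin, TF, at -0.35 ± 0.22, CLDN11 at 0.30 ± 0.19 and INHA at -0.10 ± 0.07. Selenium handling genes had a median of 0.02 (adjusted p = 0.407), with SEPHS1 at -0.12 ± 0.07, CBS at 0.17 ± 0.10, ELAVL1 at 0.13 ± 0.08 and SARS1 at 0.13 ± 0.09. Of these genes, CYP11A1 was at 0.33, NR2F2 at -0.14, INHBA at -0.12, ELAVL1 at 0.07 and SARS1 at 0.05 without Mix animal 4, CYP19A1 at 0.18 and TF at -0.20 without Mix animal 2, and INHA at -0.05 without Mix animal 3. TF was also at -0.19 without ISe animal 1, and CLDN11 at 0.20 without ISe animal 5. The 18 lists not called had adjusted p-values from 0.103.

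Mix was compared with OSe to ask whether the mixture differed from the organic form alone. Gonocyte and spermatogonium genes lay higher in Mix in 37 of 42 members, with a median of 0.23 (camera adjusted p = 2.14e-08; adjusted p = 0.725 with an estimated correlation). ZBTB16 was at 0.48 ± 0.15 (SE), GFRA1 at 0.52 ± 0.19, DNMT3L at 0.25 ± 0.09 and DND1, an RNA-binding protein of germ cells, at 0.47 ± 0.19. Without Mix animal 3 the list mean went from 0.24 to 0.16 (adjusted p = 0.000412), and DND1 was at 0.31. Glutathione and antioxidant genes lay lower in 31 of 42 members with a median of -0.10 (camera adjusted p = 0.014; adjusted p = 0.725 with an estimated correlation). NQO1 was lower by -0.85 ± 0.18 (1.80-fold) and had the only p under 0.05 when adjusted over the list alone (0.0161), and GSTA4 was at -0.29 ± 0.09, GSS at -0.21 ± 0.07 and SOD3 at -0.56 ± 0.24. Cholesterol genes lay lower in 16 of 20 members with a median of -0.25 (camera adjusted p = 0.025; adjusted p = 0.748 with an estimated correlation). HSD17B7 was lower by -0.73 ± 0.15 (1.66-fold), the only member with a p under 0.05 when adjusted over the list alone (0.00596). For NQO1 and HSD17B7 alike, this adjustment leaves out the other lists. PMVK was at -0.30 ± 0.13, NSDHL at -0.47 ± 0.24 and TM7SF2 at -0.45 ± 0.25. Without OSe animal 3 NSDHL was at -0.13, TM7SF2 at -0.11 and the list mean went from -0.24 to -0.02 (adjusted p = 0.517), and the call also ended without Mix animal 2 or 4 (0.0588 and 0.0589).

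The other lists called in Mix against OSe lay higher in Mix. Immediate early genes did so in 24 of 32 members, with a median of 0.09 (camera adjusted p = 0.0268; adjusted p = 0.748 with an estimated correlation). Its members of smallest p went both ways, with EGR4 at 0.58 ± 0.28 (SE) and JUNB at 0.21 ± 0.11 but JUND at -0.23 ± 0.10 and BTG2 at -0.20 ± 0.11. Genes of rete testis, efferent duct and epididymal epithelium lay higher in 19 of 23 members with a median of 0.07 (camera adjusted p = 0.0268; adjusted p = 0.725 with an estimated correlation), with the epithelial keratin KRT18 at 0.59 ± 0.21, CDH1 at 0.20 ± 0.13, PAX2 at 0.20 ± 0.13 and ESR1 at -0.35 ± 0.20. Inflammation and acute phase genes lay higher in 23 of 35 members with a median of 0.08 (camera adjusted p = 0.0268; adjusted p = 0.725 with an estimated correlation), with TNFAIP3 at 0.23 ± 0.08, S100A9 at 0.27 ± 0.11, S100A12 at 0.73 ± 0.32 and NOS2 at -0.46 ± 0.17. Each of these calls, and that of the antioxidant list, ended without 3 to 5 of the 13 calves left out singly, with adjusted p-values of 0.0545 to 0.15. The calves were OSe animals 1 and 4 and Mix animals 2 and 4 for immediate early genes, OSe animals 1 and 3 and Mix animals 1 and 4 for the epithelium, OSe animals 2 and 3 and Mix animals 1, 3 and 4 for inflammation, and OSe animal 3 and Mix animals 1 and 3 for antioxidants. The immediate early mean of 0.08 went to 0.04 (OSe animal 1), 0.05 (OSe animal 4), 0.05 (Mix animal 2), 0.05 (Mix animal 4) and 0.14 (OSe animal 2) without the calf named. The epithelium mean of 0.08 went to 0.05 (OSe animal 3) and 0.13 (OSe animal 2). Without Mix animal 3, PAX2 was at 0.10, CDH1 at 0.11 and S100A12 at 0.49, and CDH1 was also at 0.11 without OSe animal 4. KRT18 was at 0.33 without Mix animal 4, ESR1 at -0.20 without Mix animal 2, BTG2 at -0.09 without OSe animal 3 and NOS2 at -0.30 without OSe animal 1. Quantile normalization ended the calls of epithelium and inflammation (0.125 for both), and inflammation had a mean of -0.01 after the dimmest 50% of probe sets were left out.

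No single gene passed the test in Mix against OSe either. In limma, 0 of 26773 probe sets had an adjusted p under 0.05 (lowest 0.291), and 2283 had an unadjusted p under 0.05, 721 higher and 1562 lower in Mix. The unmoderated model gave 0 and 2148. Without OSe animal 3, 1 probe set without a gene symbol passed, with a change of 1.86 against 1.38 in all calves (adjusted p = 0.0123). The split was 1045 higher and 1154 lower after quantile normalization and 993 and 1333 after median centring. RNF141 had the lowest p, at 9.06 ± 0.33 (SD) in Mix and 10.03 ± 0.18 in OSe, a change of -0.97 ± 0.15 (SE, 1.96-fold). Larger by size were BOLA-DQA1, a class II histocompatibility chain (-2.02 ± 0.41), and the alarmin IL33 (-1.28 ± 0.30). The locus of BOLA-DQA1 is highly polymorphic in cattle, and its other probe set, near the bottom of the scale, was at 0.36 ± 0.21. Lower too were ACOX3 (-0.45 ± 0.08), ENPP5 (-0.50 ± 0.11), the phosphatase MTM1 (-0.35 ± 0.08), MIR374B (-0.55 ± 0.13) and SPIN2 (-0.56 ± 0.13). First on the higher side were the neuropeptide galanin, GAL (0.45 ± 0.10), PITX3 (0.35 ± 0.08), MCTP2 (0.34 ± 0.08), the thioesterase ACOT7 (0.53 ± 0.14), ATP4A (0.37 ± 0.10), MAGEB4 (0.84 ± 0.24), SULT4A1 (0.81 ± 0.23), the calcium pump ATP2B2 (0.45 ± 0.13), TMEM59L (0.33 ± 0.09) and the calcium sensor NCS1 (0.39 ± 0.11). Selenoproteins were lower in 19 of 25 members with a median of -0.08 (adjusted p = 0.283), with TXNRD1 at -0.15 ± 0.07, SELENON at -0.19 ± 0.11, GPX3 at -0.13 ± 0.09 and SELENOV at -0.12 ± 0.10. Selenium handling genes had a median of 0.02 (adjusted p = 0.584), with SELENBP1 at -0.39 ± 0.20, LRP2 at 0.35 ± 0.21, PSTK at -0.20 ± 0.12 and SECISBP2 at 0.17 ± 0.13. Leydig cell genes had a median of -0.10 (adjusted p = 0.317), with HSD3B1 at -0.37 ± 0.16, CYP21A2 at -0.28 ± 0.12, SULT1E1 at 0.20 ± 0.09 and SCARB1 at -0.25 ± 0.12. Sertoli cell genes had a median of -0.05 (adjusted p = 0.283), with SOX9 at -0.33 ± 0.13, FST at 0.28 ± 0.11, TF at -0.51 ± 0.23 and INHBA at -0.28 ± 0.13. Of these genes, GPX3 was at -0.09, SELENOV at -0.05, PSTK at -0.11 and CYP21A2 at -0.16 without OSe animal 2, and HSD3B1 at -0.22 and SCARB1 at -0.14 without OSe animal 3. LRP2 was at 0.19, SECISBP2 at 0.05 and FST at 0.19 without Mix animal 3, LRP2 also at 0.19 without OSe animal 4, and INHBA at -0.18 without Mix animal 4. The 19 lists not called had adjusted p-values from 0.0684.

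**Figure D2:**
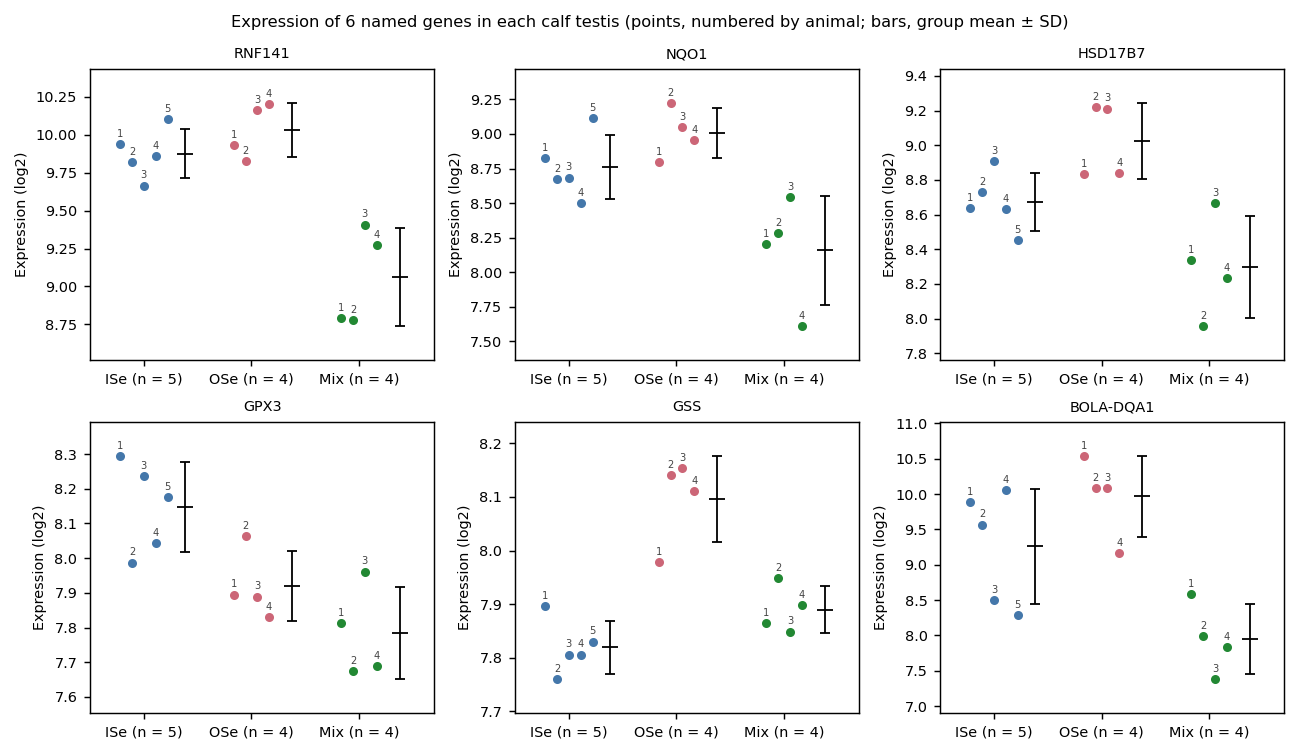
Expression (vertical axis, log2 scale) of RNF141, NQO1, HSD17B7, GPX3, GSS and BOLA-DQA1 in each calf testis, by maternal selenium form; points are calves numbered as in the labels and bars are group mean ± SD. RNF141 lies between 8.78 and 9.41 in the 4 Mix calves and between 9.67 and 10.2 in the 9 other calves.

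Mix was set against the midpoint of ISe and OSe to ask whether the mixture departed from the midpoint of the forms it was made of. A gene that lies between the forms can depart from it too. RNF141 lay below the midpoint by -0.89 ± 0.13 (SE) and had an adjusted p of 0.142, the lowest of all named genes. ACOX3 was at -0.40 ± 0.07, ZP2 at -0.47 ± 0.09, NQO1 at -0.72 ± 0.15, IL33 at -1.04 ± 0.26 and MCTP2 at 0.35 ± 0.07. In limma, 0 of 26773 probe sets had an adjusted p under 0.05 and 1981 had an unadjusted p under 0.05, 717 above and 1264 below the midpoint. The unmoderated model gave 0 and 1865. The split was 896 above and 1027 below after quantile normalization and 867 and 1229 after median centring.

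The changes of OSe and of Mix against the same ISe calves were compared across probe sets. CHST7 and NID1 lay lower than ISe in both, by -0.30 and -0.33 and by -0.29 and -0.29, and GPX3 by -0.23 and -0.36. HSD17B7 was at 0.35 in OSe and -0.37 in Mix, and IL33 at 0.48 and -0.80. The correlation over all probe sets was 0.16. Unchanged groups simulated against shared controls gave 0.44 on average (0.06 to 0.76 over 100 draws), and 4 draws lay at or below the observed value, a number that went to 23 when the simulated deviations were drawn with replacement. The covariance was 0.0035 against a simulated 0.0113, a difference of -0.0077. With the ISe calves divided between the comparisons, the correlation averaged -0.19 over 20 splits (-0.43 to 0.03) and the covariance -0.0071. Leaving out 1 calf took the correlation as far as 0.09 (OSe animal 3) and 0.33 (ISe animal 4). Leaving out the dimmest 50% of probe sets took it to 0.03. Probe sets are not independent replicates.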

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

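The tests chosen only after the result was seen were, for the cholesterol genes, those of an array-wide offset, a larger share of Leydig cells and organic selenium in the diet, and, for the gonocyte genes, those of 1 calf and of a larger share of cord tissue, and the exact permutation test. Within groups, a calf was picked out where its gap to the nearest calf took up most of the group's range (Dixon's test). Among 501 group values of 141 genes, 25 lists and the array medians, 33 were picked out, where chance gives about 25. The number of genes checked was widened to 141 after a first pass over fewer. OSe animal 2 had 7 of them, Mix animal 3 had 5, and ISe animal 3 and OSe animal 3 had 4 each.

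In OSe animal 3 the cholesterol list stood at 0.85, where the other 12 calves lay between -0.225 and 0.0417, and 14 of 20 members were above every other calf. An array-wide offset is argued against by the median of all probe sets of this array, at -0.0186. Organic selenium as the sole source is argued against by the other 3 OSe calves, which averaged -0.0507, within the range of ISe and Mix calves. A sterol-regulated programme stays open, since 11 other sterol-regulated genes, 0 of them in another list, had a median deviation of 0.531. They ran from -0.141 (ACACA) to 1.5 (ACSS2), and SREBF1 was at -0.0923. The highest of 10000 random lists matched on mean level had 0.243. Genes that vary together can pass such lists in a single calf for other reasons. A larger share of Leydig cells, which take up and make cholesterol, stays open too, with a median deviation of 0.611 over 6 Leydig cell genes (SD 0.541, from -0.0919 to 1.49), and the 2 may hold together.

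The gonocyte list was higher in Mix than in OSe, with a median of 0.229 over 42 members. Array centring left a median of 0.25, which argues against an array-wide offset, and leaving out Mix animal 3, the highest at 0.394, left 0.141, which argues against that calf as the whole cause. A larger share of seminiferous cord tissue would raise Sertoli cell genes alike, and their mean change was -0.0731, a difference of 0.314 (SE 0.124) from the gonocyte genes. A larger share of germ cells within the cords and the maternal selenium form stay open as untested hypotheses. Chance is not excluded either: the exact permutation p of the list mean was 0.0857, where the smallest possible with 4 and 4 calves is 0.0286.

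The other values picked out by Dixon's test were as follows. The test weighs a gap against the range of the group, so small gaps were picked out too. MCTP2 in Mix animal 3 was at 7.14 against 7.2 to 7.21 in its group, and HOXB9 in OSe animal 1 at 6.34 against 6.46 to 6.49. Most of the number picked out is what chance gives. OSe animal 2 had the array median of 7.74, a red blood cell list mean of 0.232, and SEMA3D at 10.1, ZNF572 at 7.89, SELENOV at 6.69, NR2F2 at 11.7 and CD79B at 6.79. The median deviation of this array from the other 12 was 0.112, which can make up part of these gaps. ZNF572 lay at 7.74 to 7.75 in the rest of its group, and SEMA3D, with a wider gap, at 9.44 to 9.47. Mix animal 3 had MCTP2 at 7.14, NCS1 at 7.29, DDX4 at 9.72, FST at 7.53 and LRP2 at 6.98. OSe animal 3 had NSDHL at 10.3, TM7SF2 at 8.55 and TEX101 at 5.55. ISe animal 3 had NCS1 at 6.78, UCHL1 at 9.89, SARS1 at 10 and EGR2 at 6.98. ISe animal 1 had a lymphocyte list mean of -0.141 and an inflammation list mean of 0.107. OSe animal 1 had HOXB9 at 6.34, GSTA2 at 6.66 and NOS2 at 8.95. ISe animal 5 had ZNF572 at 7.95 and FOSL1 at 5.91, ISe animal 4 TM7SF2 at 6.88 and ISe animal 2 GSTA4 at 10.6. Mix animal 2 had MTM1 at 9.26 and CYP21A2 at 6.91, Mix animal 1 CLDN11 at 8.21 and OSe animal 4 CDH1 at 6.26.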

How the results depend on the processing

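The runs on probe sets with 1 gene symbol, the exact permutation of list means and the other forms of the similarity simulation were chosen only after the result was seen. The 170 named gene changes were chosen by smallest p in these same data, which made a kept sign likely in advance. They kept their sign and stayed short of the threshold in all 1467 alternatives and in all 2210 runs without 1 calf. Their size was less stable: 59 of the 170 moved by over 1.5 times without at least 1 calf, and 18 of them shrank by over 2 times, as NSDHL in OSe against ISe from 0.45 to 0.12 and in Mix against OSe from -0.47 to -0.13 without OSe animal 3. In limma the adjusted counts, 0 in every comparison (701 to 2283 at an unadjusted p under 0.05), stayed at 0 without 1 calf, except 0 to 1 for the F test and for Mix against OSe (1 without OSe animal 3). Fewer probe sets tested gave fewer unadjusted calls, but not in proportion: for OSe against ISe 428 without the dimmest 25%, 270 without the dimmest 50%, 422 with 1 probe set per gene and 437 with 1-symbol probe sets. Without the dimmest 50% the others were 496 (Mix against ISe), 1464 (Mix against OSe), 1267 (midpoint) and 694 (F test). Set against the share of probe sets kept, the count fell by more in OSe against ISe. It fell by less in Mix against OSe, the midpoint and the F test. Without 1 calf, Mix against ISe ran from 674 to 1731.

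List calls moved more. An estimated correlation and fry each called 0, 0 and 0 lists in OSe against ISe, Mix against ISe and Mix against OSe. The exact permutation test also called 0, 0 and 0 (lowest adjusted p 0.954, 0.446 and 0.714), but it had little room to call any. Its smallest possible unadjusted p is 0.00794, 0.00794 and 0.0286, so 4, 4 and 15 of the 25 lists would have to reach it together. Its 0 adjusted calls thus count neither for nor against a list. Unadjusted, it gave 0, 1 and 0 lists a p under 0.05, the 1 (epithelium, 0.0238) not called by camera. Lists that camera called had permutation p of 0.198 (cholesterol), 0.635 (gonocyte) and 0.683 (collagen) in OSe against ISe. In Mix against ISe the range was 0.0556 (immediate early) to 0.262 (gonocyte). In Mix against OSe it was 0.0857 (gonocyte, inflammation) to 0.4 (cholesterol, immediate early). Quantile normalization called 4 lists in Mix against ISe. Without the dimmest 50%, 5 were called in OSe against ISe and 2 in Mix against OSe, and inflammation in Mix against OSe turned to -0.01062. Without 1 calf the calls ran from 2 to 6, 4 to 10 and 3 to 8 in the same order. The collagen mean in OSe against ISe then ran from -0.1573 to 0.02949, and camera's direction for cholesterol in both OSe comparisons turned without OSe animal 3. Gonocyte, collagen, immediate early and inflammation calls in Mix against ISe and the gonocyte call in Mix against OSe held without any 1 calf. Of these the gonocyte means moved by over 1.5 times, in Mix against ISe from 0.1767 to 0.09208 without ISe animal 3 and 0.09282 without Mix animal 3, and in Mix against OSe from 0.2411 to 0.1572 without Mix animal 3. The cause was not tested.

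The similarity of changes was -0.1917 (covariance -0.007112) with split ISe arrays, and without 1 calf 0.08991 to 0.325 (0.002304 to 0.00895). Without the dimmest 50% of probe sets it went from 0.1562 to 0.03446 and the covariance from 0.003534 to 0.0005542, and with quantile normalization it was 0.1638. Its simulated reference averaged 0.4001, 0.4417 and 0.4391 in 3 forms, with 23, 4 and 4 of 100 draws at or below the observed 0.1562, so the position in the lower tail depends on the form. The shared animal numbers do not pair the calves: of 12 pairs 1 had a correlation over 0.1 (-0.1509 to 0.1014), and ISe animal 5 has no partner. With the number as a block, 0 probe sets passed and 691, 793 and 1943 had an unadjusted p under 0.05, and the block ended the calls of selenoproteins (0.0894) and oxidative phosphorylation (0.233) in Mix against ISe and inflammation (0.0594) in Mix against OSe, and no other. A linear offset, an RNA quality covariate and an unmoderated setting of camera were not run. Signal over background could not be computed.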

Other observations

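All tests on XIST were chosen only after the result was seen, that of the calf's own blood as the third form tried (the first argued against it, the second left it open), and the genes and lists of the next paragraph were picked for their level or spread. The counts over other splits were planned.

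The brightest genes were the ribosomal protein RPL23 (mean 13.94), ACTB, the matrix genes SPARC, IGFBP7 and TIMP2, then RPS2 (13.67), GNAS (13.59), CLU (13.56) and PTGDS (13.54), the last 2 known from Sertoli and Leydig cells, INSL3 (13.44) and the imprinted RNA H19 (13.41). The median SD over the 13 calves was 0.16, and 185 of 18087 genes had an SD over 0.5. Among the widest were the bone matrix protein SPP1, from 7.157 to 11.75, the neuronal gene STMN2, from 7.141 to 10.62, and a probe set of the polymorphic BOLA genes, from 8.136 to 11.84. The interferon-induced chemokines CXCL11 and CXCL9 ran from 7.721 and 7.209 in OSe animal 4 to 11.03 and 10.71 in OSe animal 1. The interferon list ran from -0.452 in OSe animal 4 to 0.428 in ISe animal 1, and the macrophage list from -0.495 in OSe animal 4 to 0.294 in OSe animal 3.

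XIST, the RNA that silences an X chromosome in female cells, stood at 9.052 in ISe animal 2 and between 6.285 and 6.977 in the other 12 calves. Female tissue in place of testis is argued against by 6 testis genes, whose median deviation was -0.173 (-0.419 to -0.0395). More of the calf's own blood, if like that of other calves, is argued against by OSe animal 2 and Mix animals 3 and 4, with HBB at 9.71, 9.31 and 9.14 (9.4 in ISe animal 2) and HBA at 8.35, 7.61 and 7.49 (9.16): their XIST of 6.48, 6.55 and 6.45 lay below the 8.09, 7.08 and 6.9 that their lower share of blood by either globin would bring, by at least 0.451 (SD of the other 12 calves 0.178). Female blood cells, as after placental exchange with a twin sister, stay open: the red blood cell list was the highest of 13 (0.31, others up to 0.232), which does not tell a sister's blood from the calf's own, while the lymphocyte list (0.0376, others -0.241 to 0.2) and the macrophage list (0.143, others -0.495 to 0.294) were not the highest. Of 7 Y-linked genes, DDX3Y (8.25, others 8.47 to 8.98) and RPS4Y1 (7.8, others 7.87 to 8.5) lay below every other calf, while USP9Y (7.9), EIF1AY (4.84), SRY (5.34), HSFY2 (6.86) and TSPY (7.94) lay within the others' range.

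Other splits of the calves into groups of the same sizes did not exclude chance for any count. For the F test 100 of 100 splits gave at least the 0 adjusted calls found (highest other 2) and 44 of 100 the 1206 unadjusted ones (3737). For OSe against ISe 100 of 100 gave the 0 adjusted (6), 95 of 100 the 701 unadjusted (2641) and 97 of 100 the 3 lists (12). For Mix against ISe the numbers were 100 of 100 (highest other 0), 50 of 100 for 995 (3154) and 23 of 100 for 7 lists (16). For Mix against OSe they were 35 of 35 (1), 6 of 35 for 2283 (3001) and 22 of 35 for 6 lists (16), and for the midpoint 100 of 100 (16) and 14 of 100 for 1981 (2991). A count of 0 is matched by every split. Splits with several times the real count, as for the F test and OSe against ISe, point to a structure of the samples. Its source was not tested, and genes that vary together across calves were not ruled out.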
